A study of Mus musculus with 8 samples.

How the data were processed

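The samples were DBA-lectin-positive cells from mouse kidney in 4 groups of 2 libraries: WT and ADPKD, each with vehicle or 666-15. Per the labels, RNA was extracted with TRIzol from freshly isolated cells and libraries were made from oligo-dT-selected RNA, although the extraction protocol also mentions whole kidney. Per the submitters' processing notes, reads were aligned to mm10 with HISAT2 2.1.0, counted per gene with featureCounts 1.6.0 and compared with DESeq2. The annotation release, strandedness and treatment of multiply mapped reads were not given in the sources used here. The deposited table held raw counts for 55304 genes in 8 libraries. Of its gene symbols 53569 (96.9%) matched GENCODE release M21 for GRCm38, which gave gene positions and the length and GC content of the longest transcript. The vehicle columns were matched to their samples by elimination. The 37 rows of mitochondrially encoded genes held 0 counts in every library and were not usable. Total counts per library ranged from 15108793 to 19702638.

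Counts were analysed in R 4.3.3 with edgeR 4.0.16. Genes were kept by filterByExpr with a minimum count of 10 and a minimum total of 15, which left 17440. Libraries were scaled by TMM, and 1 quasi-likelihood model with robust empirical Bayes estimation was fitted to the 4 groups, with 4 residual degrees of freedom, a median prior of 8.69 and a common biological coefficient of variation of 0.138. The 5 contrasts were ADPKD against WT with vehicle, inhibitor against vehicle in ADPKD cells, the same in WT cells, ADPKD against WT with inhibitor, and the interaction. All tests were two-sided, and p-values were adjusted by the Benjamini-Hochberg method within each contrast at 0.05. Groups, contrasts, gene lists and the rule for naming genes were fixed before the data were examined. Fold changes against a group at 0 counts were bounded with a floor of 3 counts over the group, which covers counting error only.

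Lists of genes for 34 cell types and processes were tested with camera in limma 3.58.1, at a preset correlation of 0.01 and with a correlation estimated from the residuals, and with fry, which tests whether a list's genes move one way on balance. The textbook CREB-induced list shares 7 genes with the dissociation-induced list. Lists not described in the results had no comparison of their own there. For the relation between 2 contrasts, correlations across genes were set against 20 simulations without effect; genes are not independent replicates.

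The genes that could be named in each contrast were the 10 rising and 10 falling genes with the largest log2 fold change among those that passed with a mean of at least 5 CPM and no overlap between the libraries of the groups, up to 4 members of each list with the smallest p, and Creb1, Pkd1 and Pkd2. Gene models without a name were left out. The text names a subset of these, and some whose call ended when 1 library was left out were not named.

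The model was tested on simulated data with the same depth and spread, and with the same mean in every group. In each contrast 67, 67 and 66 genes were then changed by 1.5-fold, 2-fold and 4-fold, of 16786 to 16828 tested. Far more genes differed in the real contrasts, and the shares recovered and falsely called depend on how many change. The shares below therefore describe this setting only. Of genes changed 4-fold, 89.4% were recovered between genotypes with vehicle, 92.4% in each of the other 3 comparisons of 2 groups and 75.8% in the interaction. At 2-fold the shares were 70.1%, 65.7%, 62.7%, 64.2% and 46.3% for genotype with vehicle, inhibitor in ADPKD, inhibitor in WT, genotype with inhibitor and interaction, and at 1.5-fold 25.4%, 25.4%, 31.3%, 23.9% and 7.46%. The share of false calls was 9.56%, 8.96%, 8.15%, 12.4% and 10.4% in the same order, above the 5% that the threshold aims at.

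Alternatives were RLE scaling, no filter on low counts, a filter of at least 5 CPM in 2 libraries, estimation without the robust option, the replicate number as a block, a model of the 2 compared groups alone, DESeq2 1.42.0, a 2-fold minimum, and leaving out each library in turn. Removal of a transcript length or GC trend per library by lowess with a span of 0.3, and the block with 2 groups alone, were added after the data had been seen. Replicate numbers did not pair libraries across groups: the differences between replicate 1 and replicate 2 correlated at -0.0371 to 0.0806 between groups over 11199 genes. RLE moved the median log2 fold change by -0.0618 at most in size. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.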

Results

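RNA was measured in cells freshly isolated from mouse kidney that bind Dolichos biflorus agglutinin (DBA), a lectin used to enrich collecting duct cells. The mice were wild type (WT) or carried a model of autosomal dominant polycystic kidney disease (ADPKD). Each genotype received vehicle (DMSO) or 666-15, an inhibitor of the transcription factor CREB, at 5 mg/kg once daily for 5 consecutive days followed by 2 days of rest. Dosing began at postnatal day 11 and lasted 3 weeks. The labels name 4 groups of 2 libraries each, 8 libraries in all, and do not name the gene altered in the ADPKD mice. Total counts per library were 18995629 and 15984105 in vehicle-treated WT cells and 15108793 and 15778906 in inhibitor-treated WT cells. They were 19702638 and 18877518 in vehicle-treated ADPKD cells and 15750372 and 15552406 in inhibitor-treated ADPKD cells. The labels do not say that the 2 libraries of a group came from separate animals, so the spread behind the p-values may be technical, except in inhibitor-treated WT cells, whose 2 libraries differed in sex. Levels below are normalised counts scaled to library size (CPM), as mean ± SD with n = 2, and log2 fold changes are given ± SE of the fit.

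The libraries separated by genotype on the first principal component, which held 63.4% of the variance, and by treatment within each genotype on the second, which held 18.0%. Log2 CPM correlated across genes at 0.978 to 0.987 between the 2 libraries of a group. Between vehicle-treated ADPKD and vehicle-treated WT libraries the correlations were 0.836 to 0.853, and between ADPKD and WT libraries treated with inhibitor 0.913 to 0.922. One library stood apart by sex: inhibitor-treated WT replicate 2 had 17688 counts of Xist, the RNA that silences 1 X chromosome in females, and 0 counts of Ddx3y, Eif2s3y, Kdm5d and Uty, which lie on the Y chromosome. The other 7 libraries had at most 8 counts of Xist and from 1776 to 3722 of Ddx3y. Genotype and treatment in the comparisons that use inhibitor-treated WT cells were therefore not balanced for sex.

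**Figure D1:**
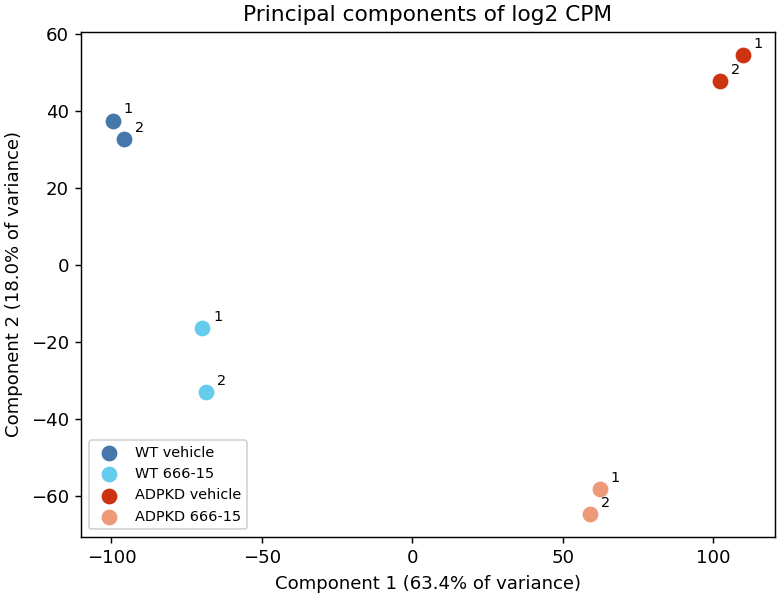
Principal components 1 and 2 of log2 CPM, with the percent of variance on each axis and 1 point per library, numbered by replicate. The 4 WT libraries lie at negative values of component 1 (-99.5 to -68.6) and the 4 ADPKD libraries at positive values (59.0 to 109.9), and the inhibitor libraries lie below the vehicle libraries on component 2.

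Creb1, the gene of the inhibitor's target (GRCm38 chromosome 1, 64532645 to 64604548), was higher in vehicle-treated ADPKD cells (74.0 ± 6.6 CPM) than in vehicle-treated WT cells (43.1 ± 2.2 CPM; log2 fold change 0.78 ± 0.11, edgeR adjusted p = 7.38e-05). With the inhibitor it fell in ADPKD cells to 53.5 ± 0.65 CPM (-0.47 ± 0.11, adjusted p = 0.0057), a call that was lost without vehicle-treated ADPKD replicate 1 (-0.37, adjusted p = 0.0552) or inhibitor-treated ADPKD replicate 1 (-0.44, adjusted p = 0.0542), and it was at -0.86 with the GC trend and -0.73 with the length trend removed. In WT cells its difference did not pass (-0.31 ± 0.12, adjusted p = 0.0733), but it passed with RLE scaling (-0.37, adjusted p = 0.0348), with a filter of 5 CPM (-0.41, adjusted p = 0.0158) and with the length trend removed (-0.38, adjusted p = 0.0364). The interaction did not pass (-0.16 ± 0.16, adjusted p = 0.512), and passed with the GC trend removed (-0.53, adjusted p = 0.0475). RNA level does not measure how active the protein was. Pkd1 (chromosome 17, 24549834 to 24596508), mutated in most families with human ADPKD, did not differ detectably between the genotypes with vehicle (66.1 ± 3.2 CPM in WT, 71.9 ± 2.3 CPM in ADPKD; 0.12 ± 0.15, adjusted p = 0.518). It fell with the inhibitor in ADPKD cells to 43.7 ± 7.4 CPM (-0.72 ± 0.15, adjusted p = 0.0027), and was at -0.54 with an adjusted p of 0.05 without inhibitor-treated ADPKD replicate 2 and at -0.37 with the GC trend removed. Pkd2 (chromosome 5, 104459450 to 104505819) was at 196.5 ± 16 CPM in WT and 178.2 ± 17 CPM in ADPKD cells with vehicle (-0.14 ± 0.10, adjusted p = 0.273). These levels neither mark nor exclude a mutation in either gene.

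What distinguishes cells of the cystic kidney from WT cells was asked with the vehicle-treated groups. Markers of the mature nephron were lower in ADPKD cells, most of all those of the proximal tubule, the segment that reclaims most of the filtrate. Slc34a1, its sodium-phosphate cotransporter, was at 3734 ± 329 CPM in WT and 4.2 ± 0.39 CPM in ADPKD cells (log2 fold change -9.80 ± 0.15, adjusted p = 3.03e-13). Proximal tubule markers held 2.58% and 2.22% of counts in the vehicle-treated WT libraries and 0.0187% and 0.0246% in the vehicle-treated ADPKD libraries. Different cells collected and different levels per cell cannot be told apart for tubule, podocyte, oxidative phosphorylation or fatty acid oxidation genes. The same holds for the other lists and genes in this comparison. Stromal markers, a list that camera did not call, had a median log2 fold change of 1.69. They held 0.042% and 0.0351% of counts in the vehicle-treated WT libraries and 0.0463% and 0.0774% in the vehicle-treated ADPKD libraries. Among single genes, Krt19, a keratin of simple epithelia, rose from 17.8 ± 3.0 to 901 ± 38 CPM (5.65 ± 0.19), Krt18 by 2.94 ± 0.10 and Muc4, a membrane mucin, by 6.46 ± 0.54. Genes of ribosomal proteins, of the p53 response and of cytokine signalling were also higher. Counts of list members adjusted over the list alone are given where they differed from those over all genes. Camera called 19 of 34 lists between the genotypes with vehicle at a preset correlation of 0.01, and 0 with an estimated correlation in any of the 5 comparisons. Of 17440 genes tested, 9842 differed at an adjusted p below 0.05, 5023 higher and 4819 lower in ADPKD cells, and 5789 of them by at least 2-fold. The balance of directions turned with RLE scaling (4762 higher, 4998 lower), without a filter on low counts (4824 and 5089), with the 2 groups alone (4619 and 5220, or 4486 and 5150 with the block), with DESeq2 (4170 and 4688) and at 2-fold (2549 and 3240). It also turned without vehicle-treated WT replicate 1 (3683 and 4042) or replicate 2 (3838 and 4154) or vehicle-treated ADPKD replicate 2 (4401 and 4662).

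All 22 measured proximal tubule markers fell in ADPKD cells (median log2 fold change -7.17; camera adjusted p = 2.40e-13, adjusted p = 0.231 with an estimated correlation). Among them were Cubn, the endocytic receptor cubilin (-6.53 ± 0.18), and Acsm2, a mitochondrial acyl-CoA synthetase (-9.31 ± 0.19). Of 11 markers of the thick ascending limb, the segment that takes up salt without water, 10 fell and 0 rose (median -3.60; adjusted p = 1.02e-06, adjusted p = 0.400 with an estimated correlation), including Egf, the epidermal growth factor precursor (2293 ± 188 CPM in WT, 4.0 ± 0.62 CPM in ADPKD), and Umod, uromodulin (-3.33 ± 0.14). Of 12 distal convoluted and connecting tubule markers 10 fell and 1 rose (median -2.78; adjusted p = 6.48e-05, adjusted p = 0.349 with an estimated correlation). Slc12a3, the thiazide-sensitive cotransporter, was at -6.14 ± 0.12 and Calb1, a calcium-binding protein, at -2.91 ± 0.18. The acid-base transporting intercalated cells of the collecting duct had 14 of 17 markers lower and 1 higher (median -2.57; adjusted p = 3.05e-05, adjusted p = 0.425 with an estimated correlation). Aqp6, an intracellular water channel, was at -2.83 ± 0.15 and Slc4a1, the anion exchanger AE1, at -8.33 ± 0.34. Principal cell markers, which define the other main cell of the collecting duct, went both ways: 7 of 14 rose and 4 fell (7 higher and 5 lower adjusted over the list alone, median 0.52, and 0.30 without vehicle-treated ADPKD replicate 1 or 0.33 without vehicle-treated WT replicate 1; adjusted p = 0.653), with the epithelial sodium channel subunit Scnn1g up by 1.0 ± 0.13, the water channel Aqp3 up by 1.11 ± 0.18 and Hsd11b2, which inactivates glucocorticoids, at -1.31 ± 0.15. Podocyte markers, such as nephrin (Nphs1, -3.90 ± 0.33), fell in 7 of 10 cases and rose in 2 (median -1.49; adjusted p = 0.0413, adjusted p = 0.596 with an estimated correlation), a call lost without vehicle-treated ADPKD replicate 2 (adjusted p = 0.0939).

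All 23 nuclear-encoded subunits of oxidative phosphorylation fell in ADPKD cells (median -1.66; camera adjusted p = 8.01e-11, adjusted p = 0.400 with an estimated correlation), among them Sdhc of complex II (-2.26 ± 0.11). All 16 fatty acid oxidation genes fell (median -1.65; adjusted p = 1.73e-07, adjusted p = 0.349 with an estimated correlation), among them Acaa2, a mitochondrial thiolase (-2.72 ± 0.12), and Cpt1a, the carnitine palmitoyltransferase that admits fatty acids to mitochondria (-2.02 ± 0.11). Of 20 interferon response genes 16 fell and 0 rose (0 higher and 17 lower adjusted over the list alone, median -2.09; adjusted p = 1.40e-06, adjusted p = 0.400 with an estimated correlation). Ifit2 was at -3.96 ± 0.26 and Gbp2 at -2.71 ± 0.15. Of 26 primary cilium genes 14 fell and 2 rose (2 higher and 15 lower adjusted over the list alone, median -0.56; adjusted p = 0.0049, adjusted p = 0.400 with an estimated correlation). The intraflagellar transport gene Ift122 was at -1.33 ± 0.15. Of 20 mitotic genes 12 fell and 1 rose (median -1.24; adjusted p = 0.0172, adjusted p = 0.582 with an estimated correlation), at low levels: Top2a, topoisomerase II, went from 10.4 ± 1.5 to 3.4 ± 0.68 CPM.

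Genes of ribosomal proteins were higher in ADPKD cells in 76 of 78 cases and lower in 0 (77 higher and 0 lower adjusted over the list alone, median 1.13; camera adjusted p = 6.04e-17, adjusted p = 0.445 with an estimated correlation). Rps19 was at 1.61 ± 0.11 and Rplp0 at 1.61 ± 0.10. Many of these genes have processed pseudogenes that can share their reads, so single members are uncertain. Ribosome biogenesis genes rose in 17 of 23 cases and fell in 0 (17 higher and 1 lower adjusted over the list alone, median 0.60; adjusted p = 4.90e-04, adjusted p = 0.445 with an estimated correlation). The nucleolar protein gene Npm1 was at 1.02 ± 0.12. Of 18 tubular injury genes 13 rose and 0 fell (median 1.80; adjusted p = 2.26e-05, adjusted p = 0.349 with an estimated correlation), including Sox9, a transcription factor of regenerating tubules (2.48 ± 0.13). Of 14 p53 targets 12 rose and 1 fell (median 1.5; adjusted p = 3.41e-04, adjusted p = 0.349 with an estimated correlation), including the cell cycle inhibitor gene Cdkn1a (320.5 ± 7.4 to 1252 ± 123 CPM) and the pro-apoptotic genes Bbc3 (2.86 ± 0.21) and Bax (1.59 ± 0.13). Of 23 cytokine and NF-kB genes 16 rose and 1 fell (17 higher and 1 lower adjusted over the list alone, median 1.46, and 0.77 without vehicle-treated ADPKD replicate 2; adjusted p = 3.41e-04, adjusted p = 0.445 with an estimated correlation). Tnf was at 5.58 ± 0.29, the interleukin-6 family member Lif at 3.19 ± 0.18 and Csf1, a macrophage growth factor, at 2.22 ± 0.11. TGF-beta and matrix genes rose in 14 of 19 cases and fell in 2 (15 higher and 2 lower adjusted over the list alone, median 1.53; adjusted p = 3.41e-04, adjusted p = 0.445 with an estimated correlation). The connective tissue growth factor gene Ccn2 was at 3.08 ± 0.18 and the membrane collagenase gene Mmp14 at 2.37 ± 0.15.

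Macrophage markers rose in 10 of 18 cases and fell in 1 (median 2.61; camera adjusted p = 0.0202, adjusted p = 0.582 with an estimated correlation), with complement C1qa at 23.0 ± 2.0 CPM and lysozyme Lyz2 at 72.3 ± 2.3 CPM in ADPKD cells against 0.57 ± 0.11 and 3.5 ± 0.85 CPM in WT cells. Dissociation-induced genes rose in 13 of 22 cases and fell in 2 (median 0.46, and 0.30 without vehicle-treated ADPKD replicate 1; adjusted p = 0.0319, adjusted p = 0.535 with an estimated correlation). Klf4 was at 1.72 ± 0.10. The call of this list was lost without vehicle-treated WT replicate 1 (adjusted p = 0.0925) and with the GC trend removed (0.35, adjusted p = 0.0945). Growth factor signalling genes rose in 12 of 20 cases and fell in 5 (median 0.56; adjusted p = 0.0476, adjusted p = 0.416 with an estimated correlation). Tgfa was at 2.30 ± 0.11 and Pdgfb at 2.68 ± 0.12. The growth factor call was lost without vehicle-treated WT replicate 1 (adjusted p = 0.0606), without vehicle-treated ADPKD replicate 2 (adjusted p = 0.0739) and with the replicate number as a block (adjusted p = 0.059). Of 24 textbook cAMP and CREB-induced genes 11 rose and 10 fell (median 0.07; adjusted p = 0.865), with a median of 0.14 and 0.04 without vehicle-treated WT replicate 1 and replicate 2 and 0.0013 without vehicle-treated ADPKD replicate 2. Areg, an EGF receptor ligand, was at 3.75 ± 0.28 and Fos at -1.10 ± 0.10. CREB family, coactivator and cAMP pathway genes rose in 13 of 23 cases and fell in 5 (median 0.60, and 0.32 without vehicle-treated ADPKD replicate 2; adjusted p = 0.0973). Fry, which does not compare a list with other genes, called this list upward (adjusted p = 0.0011). Among the genes with the largest rises, Wnt7a, a secreted Wnt ligand (chromosome 6, 91363981 to 91411363), had 0 counts in both WT vehicle libraries and 226 ± 33 CPM in ADPKD cells, at least 2794-fold higher against a floor of 3 counts over the group. Mesothelin (Msln, 7.44 ± 0.41), Anxa8 (6.91 ± 0.38) and keratin 17 (Krt17, 6.41 ± 0.31) rose from levels of 1.1 CPM or less in WT cells.

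**Figure D2:**
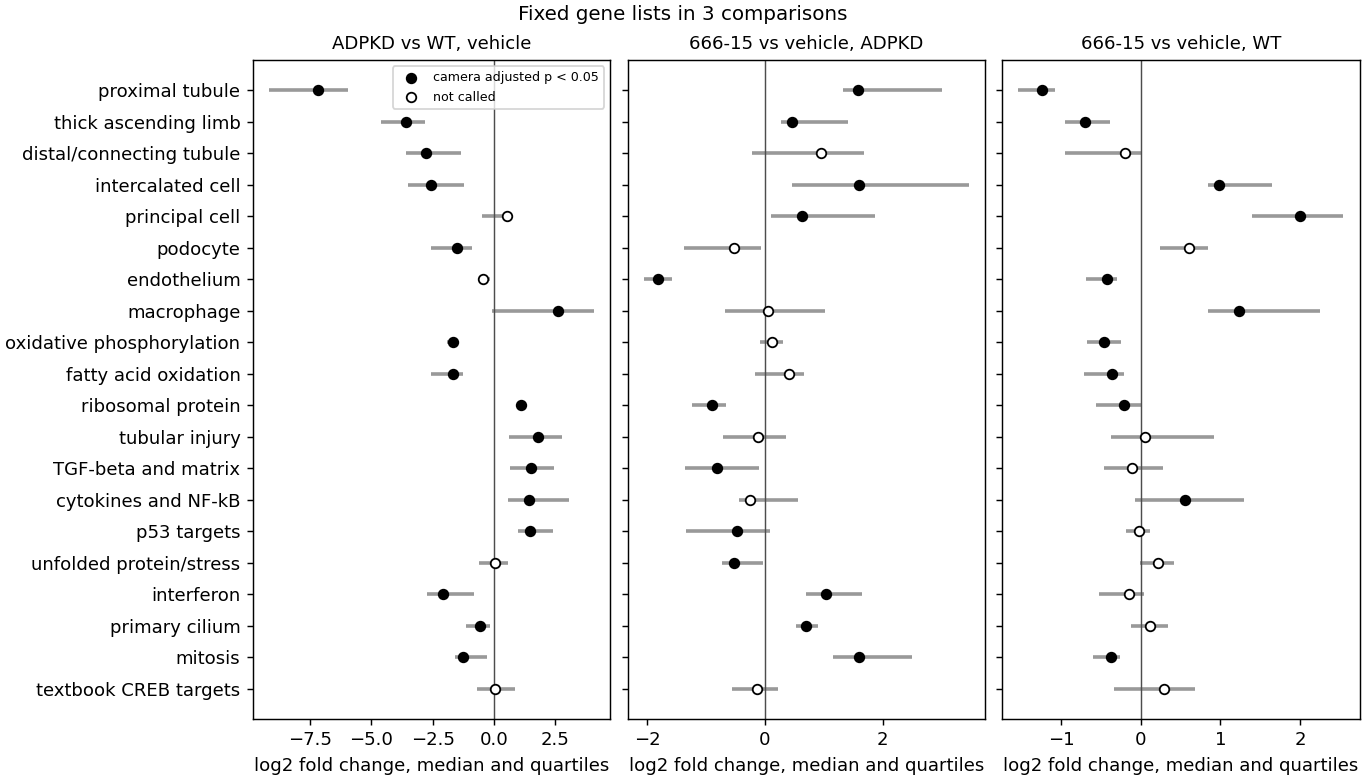
Median log2 fold change (points) and quartiles (bars) of the members of 20 gene lists in 3 comparisons, each with its own horizontal scale, with filled points for lists called by camera at the preset correlation. Proximal tubule markers have a median of -7.17 between genotypes, 1.58 with inhibitor in ADPKD cells and -1.24 with inhibitor in WT cells.

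How ADPKD cells differed with the inhibitor was read from inhibitor against vehicle in these cells. Whether the treatment lowered CREB activity was not measured. Most ribosomal protein, p53 response and endothelial genes were lower with the inhibitor. Markers of several nephron segments, mitotic genes, cilium genes and interferon genes were higher. Endothelial markers went from 0.140% and 0.171% of counts to 0.0496% and 0.0377%, and proximal tubule markers from 0.0187% and 0.0246% to 0.0671% and 0.0701%. Different cells collected and different levels per cell cannot be told apart for these markers, or for the other lists and genes in this comparison. Timp1, an inhibitor of metalloproteinases (chromosome X, 20870166 to 20874735), fell from 71.2 ± 20 to 7.0 ± 0.97 CPM (log2 fold change -3.35 ± 0.25, adjusted p = 4.08e-06). Serpina3n, a serine protease inhibitor of the acute phase, fell by 3.95 on the log2 scale. Cdkn1a fell from 1252 ± 123 to 445.6 ± 13 CPM, against 320.5 ± 7.4 CPM in vehicle-treated WT cells. Slc34a1 rose from 4.2 ± 0.39 to 41.7 ± 0.39 CPM (3.31 ± 0.13, adjusted p = 1.82e-08), with 3734 ± 329 CPM in vehicle-treated WT cells. Of the genes tested 7224 differed, 3891 higher and 3333 lower with the inhibitor, and 3218 by at least 2-fold (1537 higher, 1681 lower). More were lower also with a filter of 5 CPM (3076 and 3172) and with the 2 groups alone (3646 and 3667); without inhibitor-treated ADPKD replicate 2 the count was 4783.

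In this comparison fold changes followed the GC content of the longest annotated transcript, with a Spearman correlation of -0.35 across 17252 genes. The eighth of genes with the lowest GC content had a median log2 fold change of 0.41 and the eighth with the highest -0.48. The correlation was -0.34 in the interaction, with medians of 0.41 and -0.55 in the same eighths, and -0.21 between genotypes with inhibitor, whereas it was 0.02 for the inhibitor in WT cells and 0.09 between genotypes with vehicle. The trend with transcript length was weaker, at 0.18. With the GC trend removed 6689 genes passed for the inhibitor in ADPKD cells, 5381 of them among the 7224 called above.

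Ribosomal protein genes fell in 70 of 78 cases and rose in 0 (0 higher and 71 lower adjusted over the list alone, median -0.90; camera adjusted p = 6.45e-21, adjusted p = 0.651 with an estimated correlation). Rps19 was at -1.81 ± 0.11 and Rpl28 at -1.83 ± 0.12. Ribosome biogenesis genes fell in 11 of 23 cases and rose in 1 (1 higher and 12 lower adjusted over the list alone, median -0.32; adjusted p = 0.0194, adjusted p = 0.663 with an estimated correlation). Fbl, fibrillarin, was at -0.61 ± 0.12. The biogenesis call was lost without vehicle-treated ADPKD replicate 2 (-0.22, adjusted p = 0.147) or inhibitor-treated ADPKD replicate 1 (adjusted p = 0.0908). Of 14 p53 targets 8 fell and 1 rose (median -0.48; adjusted p = 0.0229, adjusted p = 0.651 with an estimated correlation), led by Bbc3 (-2.73 ± 0.21; -1.75 with the GC trend removed) and Bax (-1.71 ± 0.13; -0.87 with the GC trend removed). The p53 list had an adjusted p of 0.0501 without vehicle-treated ADPKD replicate 2. Of 17 unfolded protein and integrated stress response genes 9 fell and 1 rose (1 higher and 10 lower adjusted over the list alone, median -0.53, and -0.21 with the GC trend removed; adjusted p = 0.0194, adjusted p = 0.670 with an estimated correlation), with the transcription factor genes Ddit3 (-1.47 ± 0.13) and Atf4 (-0.60 ± 0.10; -0.32 with the GC trend removed) and the pseudokinase gene Trib3 (-1.19 ± 0.11; -0.76 with the GC trend removed). It was not called without inhibitor-treated ADPKD replicate 1 (adjusted p = 0.054) or by fry (adjusted p = 0.0535). TGF-beta and matrix genes fell in 9 of 19 cases and rose in 0 (median -0.82, and -0.27 without vehicle-treated ADPKD replicate 2; adjusted p = 0.0013, adjusted p = 0.651 with an estimated correlation). Ccn2 was at -1.21 ± 0.17 and the gelatinase gene Mmp2 at -1.63 ± 0.20. Stromal markers held 0.0463% and 0.0774% of counts in vehicle-treated ADPKD replicates 1 and 2, and 0.0407% and 0.038% with inhibitor. A change in the cells collected therefore stays open for the matrix genes.

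All 14 endothelial markers fell with the inhibitor in ADPKD cells (median -1.81; camera adjusted p = 1.77e-06, adjusted p = 0.651 with an estimated correlation). Flt1, a VEGF receptor, went from 190.7 ± 33 to 59.8 ± 5.9 CPM, and Plvap, a protein of fenestrated endothelium, from 157.8 ± 30 to 47.7 ± 0.51 CPM (-1.73 ± 0.21, and -1.13 with the GC trend removed). Slc7a11, the cystine-glutamate exchanger, fell from 106 ± 40 to 11.3 ± 0.01 CPM (-3.23 ± 0.49), and the metallothionein gene Mt2 fell by 3.11 on the log2 scale.

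Proximal tubule markers rose in 17 of 22 cases and fell in 1 (median 1.58, and 2.66 without vehicle-treated ADPKD replicate 2; camera adjusted p = 9.01e-07, adjusted p = 0.524 with an estimated correlation). Kap, an androgen-regulated protein of the proximal tubule, went from 1.8 ± 0.73 to 186 ± 23 CPM, and Cyp2j5, a renal cytochrome P450, from 1.2 ± 0.26 to 19.5 ± 3.6 CPM. Intercalated cell markers rose in 12 of 17 cases and fell in 0 (median 1.59; adjusted p = 1.15e-05, adjusted p = 0.651 with an estimated correlation). Aqp6 was at 3.46 ± 0.15 and Slc4a1 at 5.98 ± 0.39. Principal cell markers rose in 8 of 14 cases and fell in 1 (median 0.62; adjusted p = 0.0142, adjusted p = 0.651 with an estimated correlation). The water channel Aqp4 was at 2.73 ± 0.24 and Hsd11b2 at 2.14 ± 0.15. Thick ascending limb markers rose in 6 of 11 cases and fell in 0 (median 0.46; adjusted p = 0.0488, adjusted p = 0.670 with an estimated correlation). The potassium channel gene Kcnj1 was at 1.94 ± 0.17. The thick ascending limb call was lost without vehicle-treated ADPKD replicate 2 (adjusted p = 0.0753) or inhibitor-treated ADPKD replicate 2 (adjusted p = 0.0785). Cftr, the chloride channel of cyst fluid secretion, rose from 2.9 ± 2.6 to 37.0 ± 0.30 CPM (3.69 ± 0.58, adjusted p = 0.0039), with 47.4 ± 2.6 CPM in vehicle-treated WT cells. Of 18 tubular injury genes 3 rose and 7 fell (median -0.12; adjusted p = 0.451), and Havcr1, which encodes KIM-1, was among those that rose (1.44 ± 0.20).

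Mitotic genes rose in 16 of 20 cases and fell in 0 (median 1.6; camera adjusted p = 1.03e-05, adjusted p = 0.651 with an estimated correlation). Top2a went from 3.4 ± 0.68 to 23.9 ± 0.23 CPM, above the 10.4 ± 1.5 CPM of vehicle-treated WT cells, and Cdk1, the mitotic kinase gene, from 1.4 ± 0.72 to 8.6 ± 2.0 CPM. DNA replication genes rose in 9 of 20 cases and fell in 1 (median 0.60; adjusted p = 0.0488, adjusted p = 0.651 with an estimated correlation). The ribonucleotide reductase subunit Rrm1 was at 1.37 ± 0.15. The replication list was not called without vehicle-treated ADPKD replicate 2 (adjusted p = 0.142) or inhibitor-treated ADPKD replicate 1 (adjusted p = 0.054). Cilium genes rose in 17 of 26 cases and fell in 0 (19 higher and 0 lower adjusted over the list alone, median 0.70; adjusted p = 1.13e-05, adjusted p = 0.524 with an estimated correlation). The dynein heavy chain gene Dync2h1 was at 1.37 ± 0.20. Interferon response genes rose in 14 of 20 cases and fell in 1 (16 higher and 1 lower adjusted over the list alone, median 1.04; adjusted p = 2.31e-04, adjusted p = 0.651 with an estimated correlation). Oasl2 was at 1.91 ± 0.21 and Gbp2 at 1.5 ± 0.14. The textbook CREB-induced genes split into 4 that rose, 8 that fell and 12 that did not pass (4 higher and 9 lower adjusted over the list alone, median -0.14; adjusted p = 0.430). The median was -0.23 and 0.02 without vehicle-treated ADPKD replicate 1 and replicate 2 and -0.08 without inhibitor-treated ADPKD replicate 2. Fos rose by 1.24 ± 0.10, while Gadd45b, a stress-induced growth arrest gene, was at -1.08 ± 0.09 and Egr1 at -0.88 ± 0.11 (-0.51 with the GC trend removed). In the list of CREB and cAMP pathway genes 3 rose and 7 fell (median -0.09; adjusted p = 0.289), with a median of 0.02 without replicate 2 and -0.21 without replicate 1 of either ADPKD group. The smallest p in that list belonged to Gnas, the stimulatory G protein alpha subunit, at -2.01 ± 0.12, and fry called the list downward (adjusted p = 0.0102). CT010467.1, annotated as ribosomal RNA and chosen here after its values were seen, had 523 and 259 counts with vehicle and 3829 and 2519 with inhibitor (3.35 ± 0.35).

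**Figure D3:**
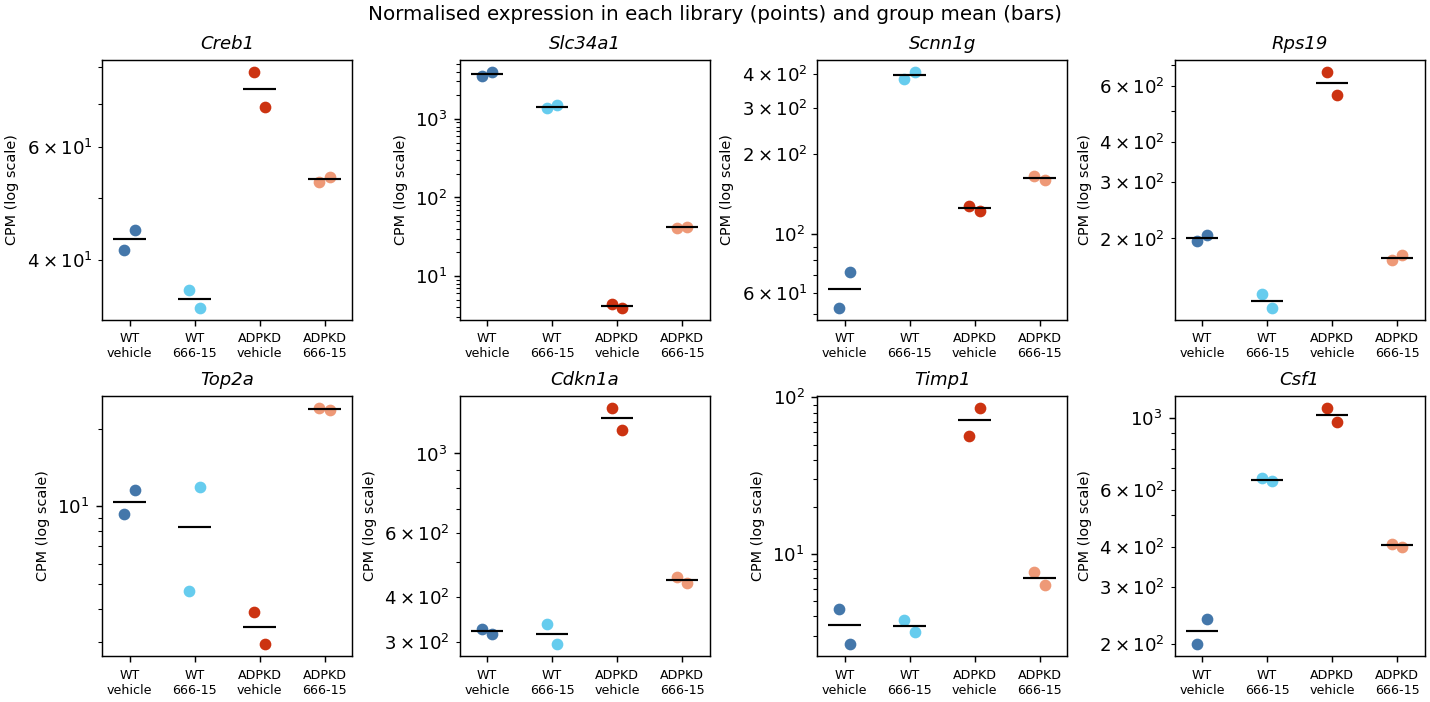
Normalised expression (CPM, logarithmic axis with its own range in each panel) of 8 genes in each of the 8 libraries as points, with the group mean as a bar. Cdkn1a, Timp1, Rps19 and Csf1 have their highest mean in vehicle-treated ADPKD cells (for Cdkn1a 1252 CPM), while Slc34a1 is highest in vehicle-treated WT cells (3734 CPM).

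The same treatment in WT cells asked what the inhibitor does without cystic disease. Principal cell markers were higher and proximal tubule markers lower. Principal cell markers went from 0.195% and 0.249% of counts with vehicle to 0.774% and 0.792% with inhibitor. Proximal tubule markers went from 2.58% and 2.22% to 0.905% and 0.945%. For segment markers, metabolic genes and the other lists and genes, different cells collected and different levels per cell cannot be told apart here. Scnn1g rose from 62.5 ± 14 to 396.6 ± 17 CPM (log2 fold change 2.67 ± 0.13, adjusted p = 2.65e-07) and Hsd11b2 from 291.3 ± 62 to 1755 ± 183 CPM (2.59 ± 0.15), whereas Slc34a1 fell from 3734 ± 329 to 1435 ± 84 CPM (-1.38 ± 0.10, adjusted p = 1.14e-06). The cytokine genes Lif and Csf1 rose by 2.83 ± 0.18 and 1.56 ± 0.11. In all 4448 genes differed, 2420 higher and 2028 lower with the inhibitor, and 1679 by at least 2-fold. The balance turned with a filter of 5 CPM (1832 higher, 2605 lower), RLE scaling (2084 and 2424), DESeq2 (1945 and 2131), the length trend removed (2126 and 2411), the GC trend removed (2228 and 2461) and the 2 groups alone with the block (2543 and 2570). The count was 3781 without inhibitor-treated WT replicate 2, the library that differs in sex, and fell to 2402 and 2887 without vehicle-treated WT replicate 1 and replicate 2.

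Principal cell markers rose in 13 of 14 cases and fell in 0 (median 2.01; camera adjusted p = 8.09e-10, adjusted p = 0.412 with an estimated correlation). The transcription factor gene Elf5 was at 2.81 ± 0.26 and Scnn1b at 2.36 ± 0.15. Intercalated cell markers rose in 10 of 17 cases and fell in 0, or 13 adjusted over the list alone (median 0.98; adjusted p = 5.09e-06, adjusted p = 0.684 with an estimated correlation). The ammonia transporter gene Rhcg was at 2.09 ± 0.24 and Aqp6 at 2.03 ± 0.13. Proximal tubule markers fell in 15 of 22 cases and rose in 0, or 20 adjusted over the list alone (median -1.24; adjusted p = 9.53e-08, adjusted p = 0.412 with an estimated correlation). Cubn was at -1.40 ± 0.13 and Acsm2 at -1.90 ± 0.13. Thick ascending limb markers fell in 7 of 11 cases and rose in 0 (median -0.70; adjusted p = 0.0053, adjusted p = 0.684 with an estimated correlation). Umod was at -1.03 ± 0.13 and the claudin gene Cldn10 at -1.51 ± 0.16. Oxidative phosphorylation genes fell in 16 of 23 cases and rose in 0 (median -0.46; adjusted p = 5.09e-06, adjusted p = 0.684 with an estimated correlation). Cox5a was at -1.04 ± 0.13 and Ndufb8 at -1.0 ± 0.12. Fatty acid oxidation genes fell in 8 of 16 cases and rose in 1 (median -0.36; adjusted p = 0.0064, adjusted p = 0.684 with an estimated correlation). The acyl-CoA dehydrogenase gene Acadm was at -0.80 ± 0.13 and its relative Acadvl at -0.77 ± 0.10. Ribosomal protein genes fell in 23 of 78 cases and rose in 6 (7 higher and 25 lower adjusted over the list alone, median -0.21; adjusted p = 0.0024, adjusted p = 0.757 with an estimated correlation). Rpl36 was at -0.90 ± 0.11 and Rps2 at -0.73 ± 0.09. Ribosome biogenesis genes fell in 6 of 23 cases and rose in 0 (median -0.24; adjusted p = 0.0246, adjusted p = 0.757 with an estimated correlation). Dkc1, dyskerin, was at -1.26 ± 0.23. The biogenesis call was lost without vehicle-treated WT replicate 2 (adjusted p = 0.0568) or inhibitor-treated WT replicate 2 (adjusted p = 0.101). Fry called neither the thick ascending limb (adjusted p = 0.0563) nor the ribosomal protein (adjusted p = 0.202) and biogenesis lists (adjusted p = 0.109).

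Cytokine and NF-kB genes rose in 10 of 23 cases and fell in 1 in inhibitor-treated WT cells (12 higher and 1 lower adjusted over the list alone, median 0.55; camera adjusted p = 0.0064, adjusted p = 0.684 with an estimated correlation), with Tnf going from 0.81 ± 0.44 to 5.5 ± 0.51 CPM. Macrophage markers rose in 7 of 18 cases and fell in 0 (9 higher and 0 lower adjusted over the list alone, median 1.24, and 0.77 without inhibitor-treated WT replicate 2; adjusted p = 0.0015, adjusted p = 0.684 with an estimated correlation). Lyz2 was at 16.2 ± 6.0 CPM against 3.5 ± 0.85 CPM, and fry did not call the macrophage list (adjusted p = 0.0716). Dissociation-induced genes rose in 9 of 22 cases and fell in 0 (11 higher and 0 lower adjusted over the list alone, median 0.30; adjusted p = 0.0107, adjusted p = 0.684 with an estimated correlation). Fosb was at 0.99 ± 0.14 and Zfp36, an mRNA-destabilising protein, at 0.95 ± 0.09. The list's median was 0.47 without inhibitor-treated WT replicate 2 and 0.26 without replicate 1, where the call was lost (adjusted p = 0.131). Glycolysis genes rose in 8 of 18 cases and fell in 1 (9 higher and 2 lower adjusted over the list alone, median 0.28; adjusted p = 0.0104, adjusted p = 0.412 with an estimated correlation). The glucose transporter gene Slc2a1 was at 1.36 ± 0.12 and Pkm at 0.75 ± 0.09. Growth factor signalling genes rose in 9 of 20 cases and fell in 2 (10 higher and 2 lower adjusted over the list alone, median 0.29; adjusted p = 0.0153, adjusted p = 0.598 with an estimated correlation). Tgfa was at 1.69 ± 0.11 and Fgfr2 at 1.89 ± 0.12.

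Camera called 4 more lists in WT cells that rested on 1 library or on few members. Endothelial markers fell in 1 of 14 cases (median -0.43; adjusted p = 0.033, adjusted p = 0.757 with an estimated correlation), at -0.09 without inhibitor-treated WT replicate 2 (adjusted p = 0.788), -0.92 without its replicate 1 and an adjusted p of 0.13 without vehicle-treated WT replicate 1. Stromal markers fell in 1 of 16 cases (median -0.72; adjusted p = 0.033, adjusted p = 0.757 with an estimated correlation), at -0.37 without inhibitor-treated WT replicate 2 (adjusted p = 0.18) and -0.41 without vehicle-treated WT replicate 1 (adjusted p = 0.13). Mitotic genes fell in 1 of 20 cases (0 higher and 0 lower adjusted over the list alone, median -0.37; adjusted p = 0.033, adjusted p = 0.757 with an estimated correlation), at -0.04 and -0.92 without inhibitor-treated WT replicate 1 (adjusted p = 0.848) and replicate 2, and not called without vehicle-treated WT replicate 2 (adjusted p = 0.0568). Neutrophil markers rose in 2 of 4 cases (3 higher and 0 lower adjusted over the list alone, median 2.1; adjusted p = 0.038, adjusted p = 0.684 with an estimated correlation), and were not called without inhibitor-treated WT replicate 2 (1.31, adjusted p = 0.107), its replicate 1 (adjusted p = 0.0825) or vehicle-treated WT replicate 1 (1.44, adjusted p = 0.133). Fry did not call the endothelial (adjusted p = 0.373), stromal (adjusted p = 0.291) or mitotic list (adjusted p = 0.207). The textbook CREB-induced genes rose in 9 of 24 cases and fell in 3 (11 higher and 5 lower adjusted over the list alone, median 0.29, and 0.14 without inhibitor-treated WT replicate 1; adjusted p = 0.148). Fry called them upward (adjusted p = 0.034), and Fos was at 0.99 ± 0.10. CREB and cAMP pathway genes rose in 5 of 23 cases and fell in 4 (6 higher and 6 lower adjusted over the list alone, median 0.19, and 0.12 and 0.11 without vehicle-treated and inhibitor-treated WT replicate 1; adjusted p = 0.501). Fry called them upward (adjusted p = 0.0335), while Gnas was at -0.79 ± 0.11. The largest rises included the calcium channel gene Trpv6 (3.28 ± 0.17) and the acetylcholinesterase gene Ache (3.43 ± 0.22), and Mt2 fell by 3.58 on the log2 scale. CT010467.1, annotated as ribosomal RNA, went from 255 and 228 counts with vehicle to 7301 and 6343 with inhibitor (5.08 ± 0.37).

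Whether the inhibitor acts alike in both genotypes was tested by the interaction, the response of ADPKD cells minus that of WT cells. Most proximal tubule, thick ascending limb, distal tubule, mitotic and interferon genes responded more upward in ADPKD cells, and most ribosomal protein and endothelial genes more downward. Slc34a1 rose in ADPKD and fell in WT cells, a difference of 4.69 ± 0.16 (log2, adjusted p = 9.38e-09), and Csf1 fell in ADPKD cells (1023 ± 73 to 405.1 ± 6.0 CPM) and rose in WT cells, a difference of -2.89 ± 0.15 (adjusted p = 3.24e-07). Scnn1g rose less in ADPKD than in WT cells (-2.29 ± 0.18). In all 4636 genes had a response that differed, 2377 upward and 2259 downward in ADPKD relative to WT cells. With the GC trend removed 4116 genes passed, 3317 of them among the 4636. The count was 5075 without inhibitor-treated WT replicate 2, and 3037 and 3073 without vehicle-treated WT replicate 1 and inhibitor-treated ADPKD replicate 2.

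In the interaction 18 of 22 proximal tubule markers passed upward (20 higher and 0 lower adjusted over the list alone, median 3.22; camera adjusted p = 3.21e-12, adjusted p = 0.271 with an estimated correlation). Acsm2 was at 4.89 ± 0.22. Also upward were 9 of 11 thick ascending limb markers (median 1.65; adjusted p = 8.64e-05, adjusted p = 0.490 with an estimated correlation) and 8 of 12 distal convoluted and connecting tubule markers (median 1.28; adjusted p = 5.21e-04, adjusted p = 0.490 with an estimated correlation). Mitotic genes passed upward in 15 of 20 cases (median 2.27; adjusted p = 2.32e-07, adjusted p = 0.490 with an estimated correlation). Ccnb1, cyclin B1, was at 3.58 ± 0.63. Interferon genes passed upward in 12 of 20 cases (median 1.29; adjusted p = 7.79e-05, adjusted p = 0.490 with an estimated correlation). Gbp2 was at 2.02 ± 0.20. Ribosomal protein genes passed downward in 62 of 78 cases and upward in 0 (0 higher and 66 lower adjusted over the list alone, median -0.75; adjusted p = 1.45e-14, adjusted p = 0.490 with an estimated correlation). Principal cell markers passed downward in 7 of 14 cases and upward in 1 (3 higher and 8 lower adjusted over the list alone, median -1.06; adjusted p = 0.0085, adjusted p = 0.490 with an estimated correlation). Aqp3 was at -2.39 ± 0.25. Endothelial markers passed downward in 9 of 14 cases (0 higher and 12 lower adjusted over the list alone, median -1.41, and -0.93 without inhibitor-treated WT replicate 1; adjusted p = 1.76e-04, adjusted p = 0.490 with an estimated correlation), a call not made by fry (adjusted p = 0.0821). Among p53 and stress genes, Bbc3 was at -2.71 ± 0.30 (-1.76 with the GC trend removed), Gdf15, a stress-induced cytokine, at -2.54 ± 0.22 and Ddit3 at -2.13 ± 0.18. The textbook CREB-induced genes passed downward in 9 of 24 cases and upward in 2 (2 higher and 10 lower adjusted over the list alone, median -0.31; adjusted p = 0.120). Fry called them downward (adjusted p = 0.0204), and Gadd45b was at -1.90 ± 0.13. CREB and cAMP pathway genes passed downward in 9 of 23 cases and upward in 1 (1 higher and 10 lower adjusted over the list alone, median -0.40, and -0.21 without inhibitor-treated WT replicate 1; adjusted p = 0.0579). Fry called them downward (adjusted p = 0.0153), and camera called them with the length trend removed (-0.31, adjusted p = 0.013). The median was -0.40 without vehicle-treated ADPKD replicate 1 and -0.41 without inhibitor-treated ADPKD replicate 1, and camera called the list in both cases.

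How far the inhibitor moved the genotype difference was asked by setting the 2 ADPKD comparisons against each other. Of the 9842 genes that differed between genotypes with vehicle, 3853 (39.1%) moved in the opposite direction with the inhibitor in ADPKD cells, some of them past the WT level, 1086 (11.03%) moved further away and 4903 did not pass. Opposite to the genotype difference moved 69 of 76 ribosomal protein genes, 26 of them past the WT level, and 12 of 13 mitotic genes, 10 of them past it. The same held for 17 of 22 proximal tubule markers, 13 of 16 interferon genes and 9 of 13 p53 targets. Differences between lists were not tested. The counts were 8 of 23 for oxidative phosphorylation genes (with 3 further away), 5 of 13 for tubular injury genes (with 2 further away) and 5 of 17 for cytokine genes (with 3 further away). They were 4 of 11 for principal cell markers (with 3 further away), 5 of 11 for distal tubule markers (with 4 further away) and 6 of 17 for growth factor signalling genes (with 6 further away). Among the 3853 genes the median size of the genotype difference was 1.29 and that of the inhibitor response 0.98 on the log2 scale. Both comparisons use the vehicle-treated ADPKD libraries with opposite sign, so chance alone gives a negative correlation. Across genes the correlation was -0.51. In 20 simulations without any effect it had a mean of -0.49 (-0.53 to -0.46), so the correlation alone does not tell reversal from chance. The covariance was -1.06 against a simulated -0.07, a difference of -0.99. With 1 of the vehicle-treated ADPKD libraries in each comparison, so that none was shared, the correlation was -0.40 and -0.41. The covariance and these unshared correlations argue against chance variation between the vehicle-treated ADPKD libraries as the whole source. Anything that both of those libraries have in common was not tested. That includes the GC trend, which was not removed for these correlations. Higher-then-lower genes numbered 1862 against 960 for independent lists and lower-then-higher genes 1991 against 1075, but the 2 same-direction counts were 670 and 416 against 1121 and 921. These counts rest on the shared libraries too. In the simulations at most 2 genes were called in both comparisons, against 4939 in the data. Without any effect few genes are called at all, so that value does not test the directions.

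**Figure D4:**
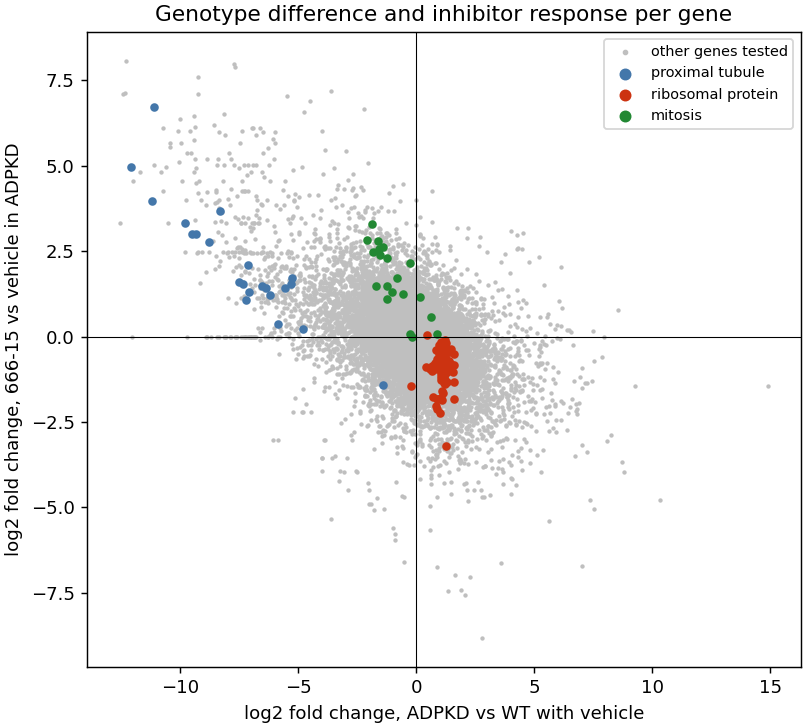
Log2 fold change of each tested gene between genotypes with vehicle (horizontal) and with inhibitor against vehicle in ADPKD cells (vertical), with members of 3 lists in colour. Most proximal tubule markers (median -7.17 and 1.58) and mitotic genes (-1.24 and 1.6) lie at the upper left. Most ribosomal protein genes (1.13 and -0.90) lie at the lower right, and the shared vehicle libraries add to a tilt in this direction by chance.

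The inhibitor responses of ADPKD and WT cells share no library. They correlated at 0.21 across genes (0.12 without vehicle-treated ADPKD replicate 2, 0.14 without vehicle-treated WT replicate 1), with 0.002 in simulations without effect, and 2603 genes were called in both. Of these 1833 (70.4%) had the same direction and 770 opposite directions. The 1143 genes that rose in both stood against 540 for independent lists, and the 690 that fell in both against 388. Those that rose in ADPKD and fell in WT cells numbered 494 against 452, and those that fell in ADPKD and rose in WT cells 276 against 462. Neither the simulations nor the independent lists include a difference in library preparation that runs with treatment. Such a difference cannot be told apart here from a shared response to the inhibitor. Gnas, Mt2, Fos, Aqp6 and Hsd11b2 passed in the same direction in both genotypes, whereas Slc34a1, Csf1, Ddit3 and Gadd45b passed in opposite directions.

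With both genotypes on the inhibitor, ADPKD cells still had lower tubule markers and higher Wnt7a, Muc4 and Esr1 than WT cells. Slc34a1 differed by -5.11 ± 0.12 (adjusted p = 4.05e-11), Egf by -6.81 ± 0.18 and Slc5a2, the glucose cotransporter SGLT2, by -5.88 ± 0.23. Muc4 differed by 7.24 ± 0.57, Esr1, the oestrogen receptor alpha gene, by 6.37 ± 0.21 (317.4 ± 21 against 3.8 ± 0.15 CPM), and Hmga2, a chromatin protein of growing tissue, by 5.11 ± 0.21. All 22 proximal tubule markers were lower (median -3.89; camera adjusted p = 2.64e-11, adjusted p = 0.297 with an estimated correlation), as were 9 of 11 thick ascending limb markers (median -2.21; adjusted p = 1.80e-05, adjusted p = 0.468 with an estimated correlation), 13 of 14 endothelial markers (median -1.83; adjusted p = 7.84e-05, adjusted p = 0.518 with an estimated correlation) and all 23 oxidative phosphorylation genes (median -1.11; adjusted p = 5.35e-10, adjusted p = 0.468 with an estimated correlation). Principal cell markers were lower in 10 of 14 cases and higher in 1 (median -1.01; adjusted p = 0.0122, adjusted p = 0.518 with an estimated correlation), and interferon genes lower in 12 of 20 and higher in 1 (2 higher and 12 lower adjusted over the list alone, median -0.80; adjusted p = 0.0049, adjusted p = 0.518 with an estimated correlation). Mitotic genes were higher in 13 of 20 cases (median 1.22; adjusted p = 1.40e-04, adjusted p = 0.468 with an estimated correlation), tubular injury genes higher in 15 of 18 and lower in 1 (median 1.04; adjusted p = 2.67e-06, adjusted p = 0.335 with an estimated correlation) and ribosomal protein genes higher in 47 of 78 (49 higher and 0 lower adjusted over the list alone, median 0.39; adjusted p = 2.46e-07, adjusted p = 0.601 with an estimated correlation). Creb1 differed by 0.62 ± 0.12 (adjusted p = 8.41e-04; 0.31 and adjusted p = 0.0663 with the GC trend removed). In all 8081 genes differed, 3804 higher and 4277 lower in ADPKD cells, and 7500 without inhibitor-treated WT replicate 2. The balance of directions turned with the GC trend removed (4082 higher, 3824 lower) and with the length trend removed (4024 and 3948), and at 2-fold it was 1398 and 2511.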

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

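Each result here is a difference between the genotypes in their response to the inhibitor, tested as an interaction (log2 fold change in ADPKD cells minus that in WT cells). The 3 patterns at the end were picked from lists with a called interaction. The comparisons with an equal inhibitor effect in both genotypes were chosen only after the result was seen. So were the tests of cells of other types and of the GC trend in mitotic genes.

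In all 4636 genes passed, with 3037 without vehicle-treated WT replicate 1 and 3073 without inhibitor-treated ADPKD replicate 2. Among lists called by camera, medians were upward in ADPKD cells for proximal tubule (3.22), mitosis (2.27), thick ascending limb (1.65), interferon (1.29), distal convoluted and connecting tubule (1.28), fatty acid oxidation (0.64), cilium (0.59), oxidative phosphorylation (0.46) and DNA replication (0.38). They were downward for macrophage (-1.59), endothelium (-1.41), podocyte (-1.08), principal cell (-1.06), cytokine (-0.97), TGF-beta and matrix (-0.93), dissociation-induced (-0.87), ribosomal protein (-0.75), unfolded protein response (-0.68) and p53 (-0.35) genes. None of these calls passed with an estimated correlation, and fry did not make those for podocyte (adjusted p = 0.0762), endothelium (adjusted p = 0.0821), macrophage (adjusted p = 0.184), DNA replication (adjusted p = 0.0872) and TGF-beta genes (adjusted p = 0.0821). Fewer than 1 in 2 members passed in the direction of the median among podocyte (3 of 10), macrophage (7 of 18), TGF-beta and matrix (7 of 19), cytokine (10 of 23), p53 (6 of 14), unfolded protein response (7 of 17), cilium (9 of 26) and DNA replication genes (5 of 20). The macrophage call was lost without inhibitor-treated WT replicate 2 (-0.73, adjusted p = 0.145), vehicle-treated ADPKD replicate 2 (adjusted p = 0.0808) or inhibitor-treated ADPKD replicate 1 (adjusted p = 0.0952). The DNA replication call was lost without vehicle-treated WT replicate 2 (0.25, adjusted p = 0.0847), inhibitor-treated WT replicate 1 (0.24, adjusted p = 0.128) or vehicle-treated ADPKD replicate 2 (adjusted p = 0.123), and its median was 0.74 without inhibitor-treated WT replicate 2. Leaving out 1 library also moved the medians of podocyte (-0.44 without inhibitor-treated WT replicate 1, -0.60 without vehicle-treated ADPKD replicate 1), endothelium (-0.93 without inhibitor-treated WT replicate 1), cytokine (-0.50 without vehicle-treated ADPKD replicate 2), unfolded protein response (-0.33 without inhibitor-treated WT replicate 2) and p53 genes (-0.19 and -0.63 without vehicle-treated WT replicate 1 and replicate 2). With the GC trend removed the dissociation-induced genes were at -0.32 and the cytokine genes at -0.58.

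Among single genes the response was more upward in ADPKD cells for Acsm2 (4.89), Slc34a1 (4.69), Ccnb1 (3.58), Top2a (3.13), Cdk1 (3.09), Havcr1 (3.08), Cubn (2.87), Egf (2.34), Oasl2 (2.25), Gbp2 (2.02) and Pkd2 (0.43). It was more downward for Timp1 (-3.30), Csf1 (-2.89), Bbc3 (-2.71), Gdf15 (-2.54), Aqp3 (-2.39), Scnn1g (-2.29), Ddit3 (-2.13), Lif (-2.09), Gadd45b (-1.90), Cdkn1a (-1.47), Plvap (-1.43), Trib3 (-1.41), Rps19 (-1.16) and Rplp0 (-1.05). The Pkd2 call was lost in 6 of the 8 cases with 1 library left out, with values from 0.36 without vehicle-treated ADPKD replicate 2 (adjusted p = 0.134) to 0.53 without vehicle-treated WT replicate 1 (adjusted p = 0.053). It was also lost with the replicate block (0.43, adjusted p = 0.0541), without the robust option (adjusted p = 0.0561) and with the length trend removed (0.37, adjusted p = 0.0809). With the GC trend removed, Bbc3 was at -1.76, Trib3 at -0.93 and Plvap at -0.79 (adjusted p = 0.0481).

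Ribosomal protein genes were lower with the inhibitor in ADPKD cells (median -0.90). A trend between libraries with transcript length or GC content was argued against as the whole cause, since the median was -0.64 with the length trend removed (quartiles -0.99 to -0.37) and -0.74 with the GC trend removed. The WT median was -0.21 and the interaction median -0.75 (quartiles -0.92 to -0.54). The list was picked for its called interaction, so these values are no further test of an equal effect in both genotypes. Reads shared with pseudogenes were not tested and stay open, as does a change in the cells collected. A response of ADPKD cells to the inhibitor may be the source, as a hypothesis.

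Proximal tubule markers were lower with the inhibitor in WT cells (median -1.24). The library of the other sex was argued against as the cause, since the median without it was -1.50. The ADPKD median was 1.58 and the interaction median 3.22 (quartiles 2.49 to 4.63). Since this list too was picked for its called interaction, an equal effect in both genotypes was not tested further. A lower share of proximal tubule cells among those collected and lower expression per cell cannot be told apart. The spread of fold changes between members beyond their standard errors was 0.309 (95% interval 0 to 0.442), which allows 1 factor for all markers as well as different factors. The lectin selection may thus have carried over fewer of these cells.

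Mitotic genes were higher with the inhibitor in ADPKD cells (median 1.6). The median was 1.70 with the length trend removed and 1.78 with the GC trend removed, which argues against either trend as the cause. More macrophages, stromal or endothelial cells were argued against by the highest median of their 3 marker lists, 0.0554 for macrophages (quartiles -0.68 to 1.02). More division within an unchanged number of these cells was not tested. The WT median was -0.37 and the interaction median 2.27 (quartiles 1.46 to 3.14). As the mitotic list was picked for its called interaction, these values do not test an equal effect in both genotypes anew. As a hypothesis, more dividing epithelial cells among those collected may be the source. A change in the mix of epithelial cells was not tested and stays open.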

How the results depend on the processing

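The transcript length and GC trends, and the block with 2 groups alone, were tried only after the data had been seen. Over 173 gene results and 2474 alternatives, 2440 kept their direction and side of the threshold, 22 no longer passed, 10 newly passed and 2 changed sign. Over 87 list results and 954 alternatives, 822 kept both, 9 newly passed and 123 were no longer called, 78 of these with an estimated correlation, which ended all 78 list calls. Apart from Creb1, Pkd1 and Pkd2, most of the tallied genes were chosen for large changes or small p. Some genes whose call ended with a library left out were not named. The gene tally therefore describes the chosen genes only and does not measure how stable calls were among all genes tested.

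The 2 changes of sign concerned Pkd1 where it had not passed: -0.02 (-0.0165, adjusted p = 0.925) between genotypes with vehicle once the GC trend was removed, and 0.06 (0.0585, adjusted p = 0.825) for the inhibitor in WT cells without inhibitor-treated WT replicate 2. That last value ranged from -0.38 without inhibitor-treated WT replicate 1. The cause was not tested.

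Requiring a 2-fold change gave 5789 genes between genotypes with vehicle, 3218 for the inhibitor in ADPKD cells, 1679 in WT cells, 3909 between genotypes with inhibitor and 2570 in the interaction, fewer by construction. Leaving out 1 library gave 7725 to 9063, 4783 to 6291, 2402 to 4016, 5799 to 7500 and 3037 to 5075 genes in the same order. The lowest counts came without vehicle-treated WT replicate 1, inhibitor-treated ADPKD replicate 2, vehicle-treated WT replicate 1, inhibitor-treated ADPKD replicate 1 and vehicle-treated WT replicate 1. A group left with 1 library was assumed to vary like the others, and fewer samples give less power. With the replicate block the counts were 9782, 7198, 4458, 8014 and 4599, and with DESeq2 8858, 6426, 4076, 7324 and 4239. RLE scaling gave 4508 genes for the inhibitor in WT cells. The balance of higher and lower genes there, 2420 and 2028, turned with a filter of 5 CPM (1832 and 2605), RLE (2084 and 2424), DESeq2 (1945 and 2131), the length or GC trend removed (2126 and 2411, 2228 and 2461) and the block with 2 groups alone (2543 and 2570). In the interaction it turned under none of the alternatives run.

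The correlation of the inhibitor responses of the 2 genotypes ranged from 0.121 without vehicle-treated ADPKD replicate 2 to 0.213 without inhibitor-treated WT replicate 1, and the cause was not tested. That between the genotype difference and the inhibitor response in ADPKD cells ranged from -0.65 to -0.45. Depth limited genes with few counts. At 1.5-fold most simulated changes were missed, in a setting with far fewer changed genes than in the data.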

Other observations

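The relation between the inhibitor response of WT cells and the genotype difference was added only after the data had been seen. Both use the vehicle-treated WT libraries with the same sign, so chance alone gives a positive correlation. Across genes it was 0.35, with 0.489 in simulations without effect, and the covariance was 0.55 against a simulated 0.07. With 1 vehicle-treated WT library in each comparison, so that none was shared, it was 0.29 and 0.28. Of 3294 genes called in both, 2634 (80.0%) had the same direction and 660 opposite directions.

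Lars2, annotated as protein-coding, and CT010467.1, annotated as ribosomal RNA, chosen for all comparisons but that of WT cells after their values were seen, had higher counts in all 4 inhibitor libraries than in the 4 vehicle libraries. Lars2 had 591 and 465 counts in WT cells with vehicle and 5157 and 5208 with inhibitor, and 300 and 169 against 2974 and 1841 in ADPKD cells. CT010467.1 had 255 and 228 against 7301 and 6343 in WT cells, and 523 and 259 against 3829 and 2519 in ADPKD cells. The log2 fold change of Lars2 was 3.68 in ADPKD and 3.56 in WT cells (interaction 0.12, adjusted p = 0.849), and that of CT010467.1 was 3.35 and 5.08. Total counts were also lower in the 4 inhibitor libraries (15108793 to 15778906) than in the 4 vehicle libraries (15984105 to 19702638). A difference in library preparation that runs with treatment was not tested and cannot be told apart from an effect of the inhibitor.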
